A study of Mus musculus with 161 samples.

How the data were processed

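Single-cell RNA sequencing was available from sorted cells of mouse pancreas. The droplet data held 5 libraries, 3 from KC mice and 2 from KPouC mice, each taken as 1 mouse from its own mouse number. KC mice carry KrasG12D with Ptf1aCre, and KPouC mice carry in addition floxed alleles of Pou2f3, the transcription factor that tuft cells require. All 5 mice were caerulein-treated and aged 8 to 9 weeks, and live EpCAM-negative cells were sorted as CD45-positive immune and CD45-negative stromal cells, per the labels. The source field of the KPouC samples also carries the abbreviation KC, so genotype was taken from the full allele list and the titles. Tuft cells, sorted as SiglecF-positive, EpCAM-positive and CD45-negative, came from 3 KC mice aged 8 to 10 months and were sequenced singly with Smart-seq2.

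The droplet files hold deposited counts of unique molecular identifiers (UMIs) per gene and barcode, and every value was checked to be a whole number. The tuft cell file holds deposited natural log values: exponentiating and subtracting 1 gave sums of 10000 per cell, so each value is the natural log of 1 plus reads scaled to 10000 per cell. Cell Ranger 3.1.0, Seurat 3.1.4, STAR 2.5.3a, HTSeq 0.9.1 and the mm10 build are named per the submitters' processing notes, which do not say which tool made which file. Of 156 labelled tuft cells, 139 had a column, and 17 without one are not analysed here. Reads per tuft cell were recovered by taking the smallest value of each cell as 1 read, and 100% of the values then came out whole within 0.01. The file lists 10876 genes, each seen in at least 3 cells. Gene positions are from GENCODE vM21 on GRCm38.

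Droplet cells needed at least 200 genes and at most 20% mitochondrial counts. Scrublet's own threshold called 1 to 60 cells per library, which did not separate a doublet population, so the highest-scoring cells were removed at 0.8% per 1000 barcodes. Of 24586 barcodes, 525 failed the filter, 972 were removed as doublets and 23089 cells were kept. Counts were scaled to 10000 per cell, and 2000 variable genes, 30 principal components and 15 neighbours gave 36 Leiden clusters at resolution 1. A cluster took the class of its best-scoring marker list when at least 3 markers were detected, each in at least 10% of its cells and more than 2-fold over the other cells with a pseudocount of 20 CPM. It stayed unnamed where its top 10 genes held more markers of another class. Of the 36 clusters, 7 stayed unnamed and held 8.75% of cells. Class names rest on these markers, since no deposited label gives a cell type, so each means cells like that type.

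Counts were summed per library and class, because cells are not replicates, and a class was tested where every library held at least 20 cells. Sums were fitted with edgeR's quasi-likelihood test after filterByExpr and TMM normalization, with Benjamini-Hochberg adjustment within the class at 0.05. Differences are KPouC minus KC on the log2 scale. Class shares were compared by exact permutation of the library labels, 2-sided; with 10 splits of 3 against 2 libraries the smallest p is 0.2. Shares were taken within the CD45-positive and the CD45-negative classes, because the sort sets the ratio between these. No label gives a droplet cell's gate, so a cluster counted as CD45-positive where its summed Ptprc counts exceeded those of Sparc. Other clusters counted as CD45-negative stroma, apart from those of epithelial or erythroid class, which counted in neither. Gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all 155 pairs of list and class with at least 5 tested members. Camera compares a list with the other genes of the class. With an estimated correlation 0 of the 57 calls held, with 15 of 155 unadjusted p under 0.05 and a smallest adjusted p of 0.451. Limma's fry asks whether a list's genes move one way on balance and compares them with no other genes; it kept 1 call, with 30 of 155 unadjusted p under 0.05. Whether the genotype effect differed between fibroblasts and macrophages was tested as an interaction in edgeR with library as a block.

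The 28 gene lists, the marker lists of 21 cell types, the tests and the rule for naming genes were written before the data were examined. Named in each class were the 10 largest increases and 10 largest decreases among genes past the threshold without overlap between groups. Where fewer than 5 genes passed, the smallest p served instead. Passing list members and 9 prostaglandin, Kras and Pou2f3 genes were always included. Unnamed gene models, Rik symbols and antigen receptor segments were counted only.

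The edgeR step was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. It recovered 68% of 2-fold and 96% of 4-fold changes in macrophages, 71% and 87% in fibroblasts, 66% and 95% in endothelial cells, and 66% and 91% in mural cells. It recovered 53% and 87% in B cells, 58% and 91% in T cells, 30% and 88% in dendritic cells, 47% and 89% in monocytes, 28% and 86% in neutrophils, and 30% and 76% in gamma-delta T or innate lymphoid cells. False calls numbered 3 to 10 per class. Counts were drawn gene by gene with the fitted dispersion trend. Spread particular to a gene and shifts shared by many genes of a library were therefore not simulated.

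For tuft cells, the share of cells with a read was given with an exact Clopper-Pearson 95% interval, which covers counting error only. No label ties a cell to one of the mice, so there is 1 sample and no test. A count of 0 was given a floor of 3 counts over the group.

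Alternatives fixed beforehand were RLE factors, no low-count filter, DESeq2's Wald test, mouse number series as a covariate, no doublet removal, a filter of 500 genes and 10% mitochondrial counts, Leiden resolution 0.5, equal cell numbers, each library left out, an estimated correlation, fry, other share denominators and, for tuft cells, other detection rules and cell sets. Added after the data were seen were a sex-linked covariate, removal of genes at under 10% of their level in another class, clusters fitted alone, non-lymphoid cells as a denominator and cluster c17 counted as fibroblasts. Software was Python 3.11.15 with Scanpy 1.11.5, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and Matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.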

Results

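Immune and stromal cells of caerulein-treated pancreas were profiled in 3 KC and 2 KPouC droplet libraries, and tuft cells of older KC mice were profiled singly. The droplet comparison asks how cells around KrasG12D-driven lesions differ when Ptf1aCre acts on floxed Pou2f3 alleles in the epithelium; no deposited file measures tuft cells in KPouC mice. KC replicates 1 to 3 held 21178158, 24128328 and 21290340 counts, and KPouC replicates 1 and 2 held 27828840 and 31253626. Median counts per kept cell were 3114, 3383 and 3337 in KC and 3355 and 5918 in KPouC. Kept cells numbered 4504, 4785 and 4205 in KC and 5016 and 4579 in KPouC.

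Pou2f3 (chromosome 9, 43123939 to 43210369, GRCm38) gave 3, 2 and 1 counts in the KC libraries and 1 and 7 in the KPouC libraries. These counts check nothing, because Ptf1aCre acts in the epithelium and the sort removed EpCAM-positive cells. Xist gave 8532 counts in KC replicate 3 and 9425 in KPouC replicate 1, and at most 2 elsewhere, so both groups held both sex-linked patterns.

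Mural cells took a larger part of the CD45-negative stroma in KPouC than in KC, and fibroblasts a smaller part. Mural cells made up 4.43% ± 0.391 (SD, n = 3) of stromal cells in KC and 20.5% ± 0.291 (SD, n = 2) in KPouC. Fibroblasts made up 65.3% ± 6.98 in KC and 42.2% ± 5.00 in KPouC, or 68.7% and 53.4% with the unnamed cluster c17 counted among them. Neither group's libraries overlapped for mural cells or fibroblasts, but the exact permutation p was 0.2 for both, the smallest that 10 splits allow. With c17 counted among fibroblasts, the lowest KC library lay at 60.55% and the highest KPouC library at 60.43%. Cluster c17 alone rose from 3.415% to 11.22% of stromal cells. The clusters of the fibroblast class did not move alike. Cluster c6 fell from 31.8% to 5.29% of stromal cells and c11 from 15.0% to 9.20%, while c5 rose from 18.5% to 27.7%. EdgeR's quasi-likelihood test on cell counts gave adjusted p of 3.13e-05 for mural cells, with a log2 change of 2.21, and 0.0173 for fibroblasts, with -0.62. Fitted among the stromal clusters in place of the classes, the same mural counts gave adjusted p = 0.002655 by this test. In that edgeR fit adjusted p was 0.0244 for both c6 and c17, 0.119 for c11 and 0.15 for c5. Fibroblasts with c17 were not tested this way. Endothelial cells were 22.5% ± 5.23 and 18.0% ± 2.93 (exact permutation p = 0.4). These are shares within the clusters assigned to CD45-negative stroma by their RNA, so a rise in one class lowers the others. Mural cells are cluster c12 alone, which Rgs5 and Acta2 lead, and both of these genes differed between genotypes. Acta2 in mural cells lost its call without KC replicate 3 (edgeR adjusted p = 0.108).

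Macrophages took a larger part of the CD45-positive cells in KPouC, and T and B cells a much smaller part in KPouC replicate 2. Macrophages were 16.0% ± 4.57 in KC and 37.3% ± 20.6 in KPouC, with 22.7% and 51.9% in the separate KPouC libraries (exact permutation p = 0.2). T cells were 34.8% ± 5.01 in KC, and 33.0% and 4.44% in KPouC replicates 1 and 2 (exact permutation p = 0.4). B cells were 25.0% ± 3.03 in KC, and 21.5% and 4.25% in KPouC (exact permutation p = 0.2). Among non-lymphoid CD45-positive cells, a denominator chosen after the data were seen, macrophages were 43.6% ± 4.36 in KC and 56.5% ± 1.68 in KPouC (exact permutation p = 0.2). The unnamed cluster c9 of 901 cells, whose best-scoring list was macrophage, is not counted there. It fell from 14.2% to 8.47% of the non-lymphoid cells, so the rise would be smaller with it counted as macrophages. Without KPouC replicate 2 the macrophage difference was 6.73 percentage points against 21.3 with all libraries, and without KPouC replicate 1 it was 35.9. The T cell difference was -16.0 points with all libraries, -1.70 without KPouC replicate 2 and -30.3 without KPouC replicate 1. The B cell difference was -12.2 points with all libraries, -3.58 without KPouC replicate 2 and -20.8 without KPouC replicate 1. EdgeR's quasi-likelihood test on cell counts called none of the CD45-positive classes, with adjusted p of 0.284 for macrophages and 0.414 for both T and B cells and log2 changes of 1.22, -0.89 and -0.96. Monocytes were 2.94% in KC and 6.40% in KPouC (exact permutation p = 0.2), and neutrophils 3.96% and 8.15% (exact permutation p = 0.4); KPouC replicate 2 held 9.50% and 12.4%. Dendritic cells were 6.46% and 4.77%, and NK cells 0.713% and 0.336% (exact permutation p = 0.2 for both). Among non-lymphoid cells, monocytes were 8.23% and 9.31% (exact permutation p = 0.6) and neutrophils 11.0% and 11.7% (exact permutation p = 0.8), so their rise was mostly absent there, while dendritic cells were 18.3% and 8.10% (exact permutation p = 0.2).

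**Figure D1:**
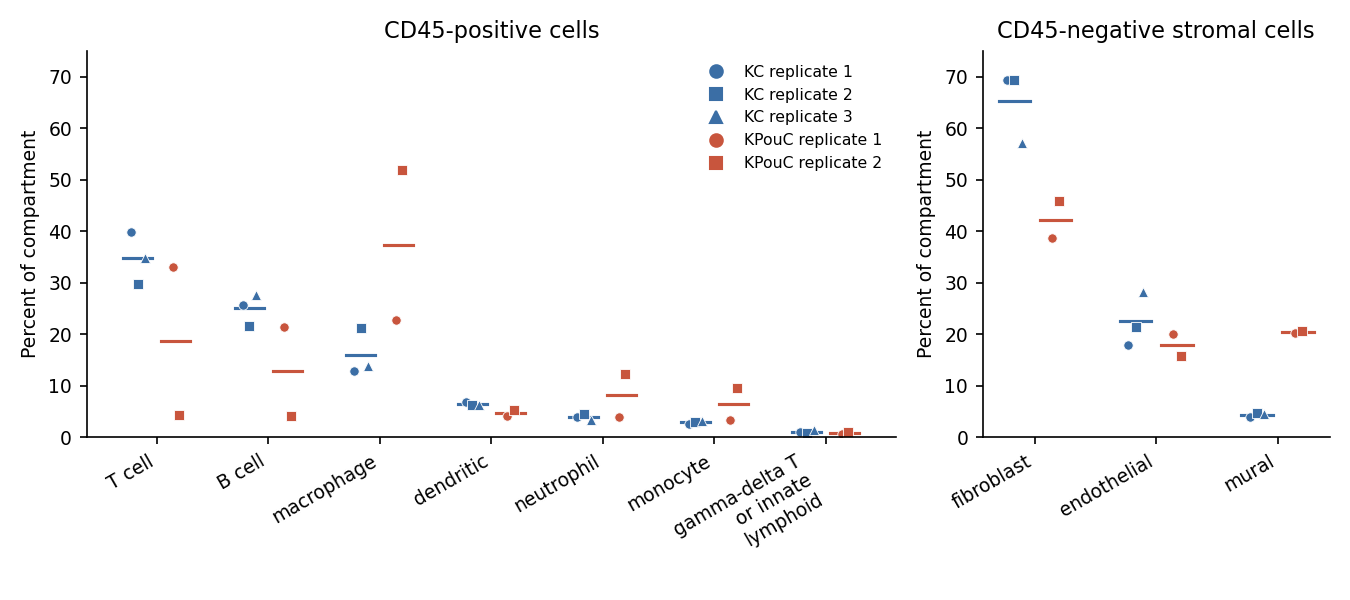
Percent of CD45-positive or of CD45-negative stromal cells, as assigned by Ptprc and Sparc counts per cluster, in each class. Each library has 1 point, with a line at the group mean. Mural cells sit near 20% in both KPouC libraries and under 5% in all KC libraries, while T and B cells are lowest in KPouC replicate 2.

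In KPouC macrophages, transcripts of alternatively activated macrophages fell, and Il1a, Il1b and the chemokine gene Ccl17 rose. Retnla (chromosome 16, 48842551 to 48844461) fell from 991 ± 530 to 143 ± 37.5 CPM, a log2 change of -2.79 (edgeR adjusted p = 0.00602). Ccl8 (chromosome 11, 82115185 to 82116799) fell from 1246 ± 65.6 to 330.1 ± 3.61, a log2 change of -1.92 (edgeR adjusted p = 0.000228). Folr2 fell from 149 to 26.0 CPM, and F13a1, Cd163, Lyve1 and Cd209f fell by 1.96, 2.01, 2.64 and 3.02 on the log2 scale. Ccl17 rose by 2.20 (edgeR adjusted p = 0.000492), Plet1 by 2.56, Cd274 by 1.16 and Il1a, which lay under 10% of its level in neutrophils, by 1.77. Epcam rose by 2.79, from 2.92 to 20.2 CPM, and Cdh1 by 2.29, although the sort took EpCAM-negative cells. Apart from Il1b, the genes in this paragraph kept their call with each library left out. Il1b rose from 706 to 2140 CPM, a log2 change of 1.60 (edgeR adjusted p = 0.0185), and lost its call without KC replicate 1 or KPouC replicate 2, where the highest adjusted p was 0.0841. Tslp fell by 2.59 in macrophages.

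Of 10473 genes tested in macrophages, edgeR called 439 higher and 448 lower in KPouC at an adjusted p under 0.05. DESeq2 called 425 and 355. Groups did not overlap for 886 of the calls and for 43.2% of all tested genes, where chance gives 20%. The total of 887 fell to 439 without KC replicate 1, 432 without KC replicate 2, 324 without KPouC replicate 1 and 483 without KPouC replicate 2. Of the 84 named macrophage genes that passed, 44 kept their call with each library left out. Calls lost numbered 26, 22 and 11 without KC replicates 1 to 3, and 29 and 25 without KPouC replicates 1 and 2. The 44 that kept their call include acinar genes such as Clps, Cpa1 and Ctrb1. Pla2g1b, also among the 44, was tested in only 3 of the fits with a library left out. Without genes at under 10% of their level in another class, 383 were higher and 324 lower. The mice fall into 2 series of mouse numbers, and with that series as covariate 823 macrophage genes passed, against 1778 with every gene that had a count, 1486 with a stricter cell filter and 506 with equal cells per library. Of 259 named calls over the classes, 49 were lost with it, among them Arg1 in macrophages, but none of the genes said here to keep their call with each library left out.

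The macrophage class joined cluster c1, which rose from 37.0% to 64.7% of it, cluster c4, at 43.1% and 31.7%, and cluster c15, which fell from 19.9% to 3.61%. The unnamed cluster c9, with Retnla and Mrc1 among its leading genes, lies outside the class. Ccl17, Plet1 and Ccl24 are among the leading genes of c1, and Ccl8, Folr2, F13a1, Cd163, Lyve1, Mrc1, Pf4 and Stab1 of c15. Their class changes therefore include the change in mix. Fitted in c1 alone, Ccl17 rose by 1.55, Plet1 by 1.95 and Folr2 and Ccl8 changed by -1.78 and -2.23, all past the threshold, while Ccl24 rose by 1.20 without passing it. In c15 alone, Folr2 changed by -0.89, Ccl8 by -0.35, F13a1 by -0.28, Lyve1 by -0.51 and Cd163 by -0.95, none past it. In c1, c4 and c15 alone, Mrc1 changed by -0.06, -0.09 and -0.09, Pf4 by -0.37, -0.51 and -0.06, and Stab1 by -0.36, -0.08 and -0.53, none past it, against -0.54, -1.31 and -0.99 in the class. F13a1 changed by -0.87 in c1 and -0.82 in c4 and Ccl8 by -0.15 in c4, none past it either. Folr2 changed by -1.39 in c4 and Ccl17 by 6.42 in c15, both past the threshold. In c4 alone, Cd163 changed by 0.46, Lyve1 by 0.12 and Ccl24 by -0.79, against their direction in the class. Cd274, Cd80, Lta4h and C4b also had the opposite sign in c4, as did Arg1 in c1 and Sell in c15. Of the class calls tested in each cluster, 99.0% had the same sign in c1, 97.2% in c4 and 93.6% in c15, clusters that are parts of the class. Called there with that sign were 107 of 804, 71 of 760 and 21 of 590.

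**Figure D2:**
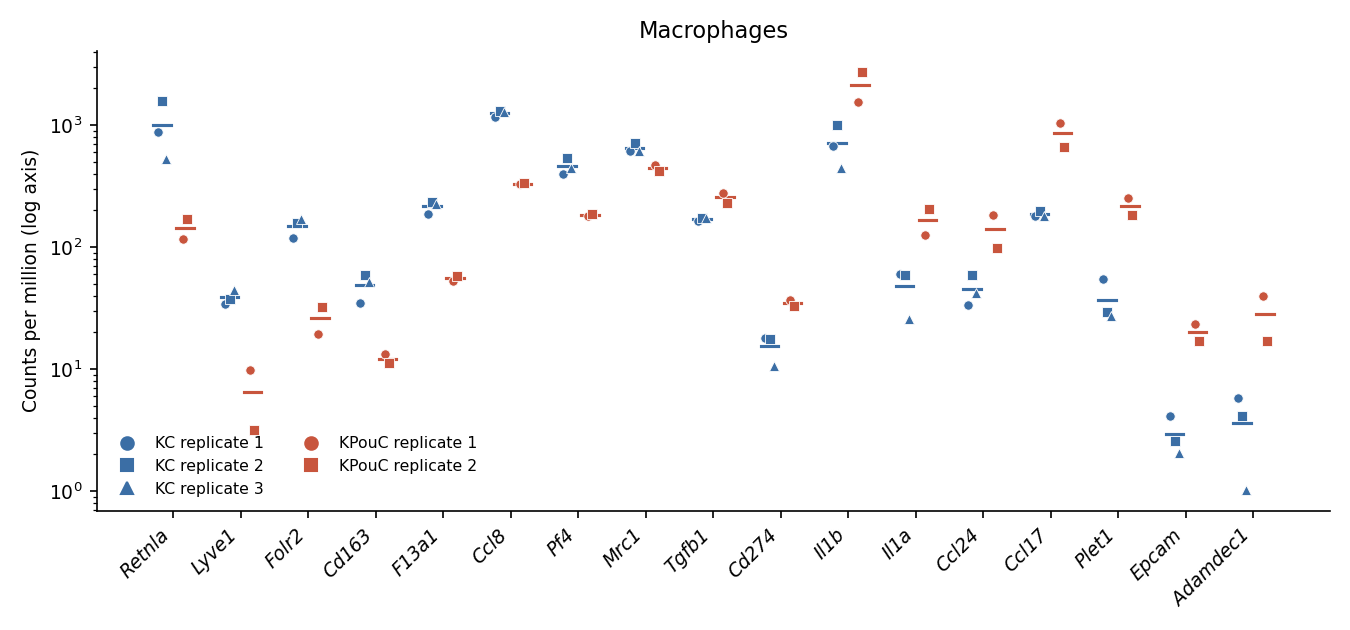
CPM of named genes in macrophages on a log axis, with 1 point per library and a line at the group mean. Ccl8 lies near 1246 in KC and 330.1 in KPouC, and Ccl17 near 186 and 854.

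Among the gene lists in macrophages, alternatively activated macrophage genes fell, with 11 of 17 lower and 3 higher by edgeR. Adjusted over the list alone these were 12 and 5, and camera gave adjusted p = 3.03e-13, and adjusted p = 0.451 with an estimated correlation. The 3 higher genes were Arg1, Ccl24 and Tgfb1, and Arg1, at 0.44, lost its call without every library except KC replicate 3, with adjusted p up to 0.157. MHC class II genes rose, with 5 of 10 higher (7 adjusted over the list alone), camera adjusted p = 2.23e-05, and adjusted p = 0.531 with an estimated correlation. NF-kB genes rose, with 6 of 18 higher (8 adjusted over the list alone), adjusted p = 6.07e-08 by camera, and adjusted p = 0.645 with an estimated correlation. TGF-beta pathway genes rose, with 4 of 9 higher and 1 lower (7 and 1 adjusted over the list alone), adjusted p = 0.00128 by camera, and adjusted p = 0.451 with an estimated correlation. Hypoxia and glycolysis genes rose, with 5 of 14 higher (8 adjusted over the list alone), adjusted p = 0.000125 by camera, and adjusted p = 0.451 with an estimated correlation. The neutrophil maturation list rose, with 3 of 10 higher and 1 lower (3 and 2 adjusted over the list alone), adjusted p = 0.0348 by camera, and adjusted p = 0.531 with an estimated correlation. Type 2 interleukin receptor and eosinophil recruitment genes fell, with 4 of 6 lower and Ccl8 the 1 called (2 adjusted over the list alone), adjusted p = 0.0347 by camera, and adjusted p = 0.619 with an estimated correlation. By camera the neutrophil maturation list lost its call without KPouC replicate 2 (adjusted p = 0.0592), and the type 2 receptor list without KC replicate 1, KC replicate 2 or KPouC replicate 1 (adjusted p = 0.0730, 0.113 and 0.361).

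Acinar transcripts were lower in KPouC macrophages for 18 of 18 tested genes. All 18 were also lower adjusted over the list alone, with camera adjusted p = 8.28e-62, and adjusted p = 0.451 with an estimated correlation. Clps fell from 102 to 1.14 CPM and Ctrb1 from 91.8 to 6.16. Rnase1, Spink1 and Cpb1 had 0 counts in KPouC, and were at least 48.0-fold, 31.8-fold and 27.9-fold lower against a floor of 3 counts over the group. Reads of the trypsin genes Try4, Try5 and Prss2 can be shared between near-identical copies. In KC replicates 1 to 3, 40.2%, 47.4% and 47.2% of macrophages had an acinar count at median depths of 6618, 5775 and 5404. T cells, which should lack these genes, had one in 10.3%, 13.6% and 11.2% at median depths of 2829, 3026 and 3184. In KPouC these shares were 9.95% and 7.69% of macrophages and 1.25% and 2.19% of T cells. Acinar RNA therefore differed between genotypes in other classes too. The acinar list was also called lower in B cells (1 of 7, or 7 adjusted over the list alone), with adjusted p = 3.60e-18 by camera and adjusted p = 0.451 with an estimated correlation. In T cells it was 0 of 12, or 11 adjusted over the list alone, with adjusted p = 1.25e-20 by camera and adjusted p = 0.489 with an estimated correlation. In fibroblasts it was 1 of 9 (6 lower and 1 higher adjusted over the list alone), with adjusted p = 7.79e-07 by camera and adjusted p = 0.531 with an estimated correlation, and the list and its 1 called gene Clps both changed direction with a stricter cell filter. B cell markers fell in macrophages for 6 of 7 tested genes and T cell markers for 2 of 8, alongside the lower lymphocyte share.

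Fibroblasts of KPouC mice carried more myofibroblast transcripts, Acta2 and Tagln among them, and less Clec3b and Hmcn2. Acta2 (chromosome 19, 34241090 to 34255590) rose from 211 ± 29.9 to 604 ± 53.2 CPM, a log2 change of 1.51 (edgeR adjusted p = 0.00681). Tagln rose by 1.52 (edgeR adjusted p = 0.0063), Tpm2 by 1.03, Myl9 by 0.98 and Tgfb1 by 1.06. Clec3b fell by 1.84 (edgeR adjusted p = 0.00681) and Hmcn2 by 2.76. Bex1 rose by 4.81 and Igfbp2 by 3.11. These 9 genes kept their call with each library left out. Acta2 and Myl9 in fibroblasts lay under 10% of their level in mural cells, a class whose share rose. Col14a1 fell by 1.01 and lost its call without KPouC replicate 2, at adjusted p = 0.051, and in clusters c5 and c11 fitted alone. Col12a1 rose by 1.78, Ctgf by 1.76 and Lrrc15 by 2.53. Col12a1 and Ctgf lost their call without KC replicate 1, KC replicate 2 or KPouC replicate 1, and Lrrc15 without any library except KC replicate 3, with adjusted p up to 0.106, 0.0854 and 0.106. Slpi rose by 3.42 and Ccl4 by 3.35, but both changed direction without doublet removal. Trem2, Ccl4, Slpi and Ccl5 lay under 10% of their level in a leukocyte class.

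Of 11719 genes tested in fibroblasts, edgeR called 162 higher and 101 lower, and DESeq2 260 and 180. All 263 called genes were without overlap between groups, as were 37.6% of tested genes, where chance gives 20%. The total was 694 with the sex-linked pattern as covariate, 583 at Leiden resolution 0.5 and 1197 with every gene that had a count. It fell to 110 with mouse number series as covariate, where Ccl4 and Lrrc15 lost their call, and to 61 without KC replicate 1, 60 without KC replicate 2 and 120 without KPouC replicate 1. Of 47 named fibroblast genes that passed, 11 kept their call with each library left out, and calls lost numbered 30, 32 and 12 without KC replicates 1 to 3, and 22 and 23 without KPouC replicates 1 and 2. The class joined cluster c5, which rose from 28.0% to 66.2% of it, cluster c6, which fell from 49.1% to 12.0%, and cluster c11, at 22.9% and 21.8%. Clec3b, a leading gene of c11, changed by -2.17 in c5 and -1.59 in c6, both past the threshold, and by -1.15 in c11, not past it. Col14a1, also leading c11, changed by -0.99 in c5 and -0.61 in c11, not past the threshold, and by -0.79 in c6, past it. Col12a1, a leading gene of c5, changed by 1.13, 1.21 and 1.17 in c5, c6 and c11 alone, none past it. Of the class calls tested in each cluster, 99.6% had the same sign in c5, 97.3% in c6 and 99.1% in c11, which is no independent check since the clusters are parts of the class. Only 14 of 252 were also called in c5, 58 of 222 in c6 and 13 of 217 in c11. The unnamed cluster c17, whose best-scoring list was fibroblast, lies outside the class, so the fibroblast values here leave it out. Its leading genes included Tnc, Spp1, Timp1, Postn and Tagln. It had Penk, Crlf1 and Abi3bp higher, and no gene lower, among 6011 tested by edgeR. Unadjusted, 264 were lower, and DESeq2 called 5 lower.

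The myofibroblast list rose in fibroblasts, with 10 of 18 higher and none lower. Adjusted over the list alone 13 were higher, with adjusted p = 1.82e-20 by camera, and adjusted p = 0.451 with an estimated correlation. Of 7 mural cell markers tested in fibroblasts, 2 were called higher, and the median log2 change was 1.51. The 2 called were Acta2 and Tagln, which are also on the myofibroblast list, and the median is the value of Acta2. The 2 called genes are thus no separate sign of mural RNA. The inflammatory fibroblast list fell, with 3 of 18 lower (7 lower and 1 higher adjusted over the list alone), adjusted p = 0.0051 by camera, and adjusted p = 0.712 with an estimated correlation; it lost its call with mouse number series as covariate. The lipid-associated list rose, with 2 of 11 higher (6 higher and 2 lower adjusted over the list alone), adjusted p = 5.05e-05 by camera, and adjusted p = 0.451 with an estimated correlation; fry also called it, at adjusted p = 0.0229. TGF-beta pathway genes rose, with 2 of 12 higher (4 adjusted over the list alone), adjusted p = 0.00209 by camera, and adjusted p = 0.531 with an estimated correlation. Hypoxia and glycolysis genes rose, with 2 of 14 higher (8 higher and 1 lower adjusted over the list alone), adjusted p = 3.51e-05 by camera, and adjusted p = 0.572 with an estimated correlation. NF-kB genes rose, with 2 of 13 higher (3 adjusted over the list alone), adjusted p = 0.00736 by camera, and adjusted p = 0.761 with an estimated correlation. MHC class II genes rose, with 1 of 8 higher (2 adjusted over the list alone), adjusted p = 0.00215 by camera, and adjusted p = 0.722 with an estimated correlation. The proliferation list rose with 0 of 15 genes called (0 adjusted over the list alone), adjusted p = 0.0337 by camera, and adjusted p = 0.765 with an estimated correlation, and it fell without KPouC replicate 2, at adjusted p = 0.749. The fibrillar collagen list was not called in fibroblasts (camera adjusted p = 0.548). Markers of some leukocytes moved with the lipid-associated, NF-kB and MHC class II lists in fibroblasts. Median log2 changes were 1.10 for macrophage markers (0 of 6 called by edgeR), 0.82 for monocyte markers (1 of 5) and 2.25 for neutrophil markers (0 of 4). Others did not, at -2.07 for T cell markers (0 of 6), -1.48 for B cell markers (0 of 4) and 0.003 for dendritic cell markers (0 of 4). By camera the inflammatory fibroblast list lost its call without KC replicate 2 or KPouC replicate 1 (adjusted p = 0.0601 and 0.361), MHC class II without KPouC replicate 1 (0.218), NF-kB without KC replicate 1 or KPouC replicate 2 (0.0594 and 0.802) and TGF-beta without KPouC replicate 2 (0.106). Proliferation also lost its call without KC replicate 2 or KC replicate 3 (camera adjusted p = 0.180 and 0.108).

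**Figure D3:**
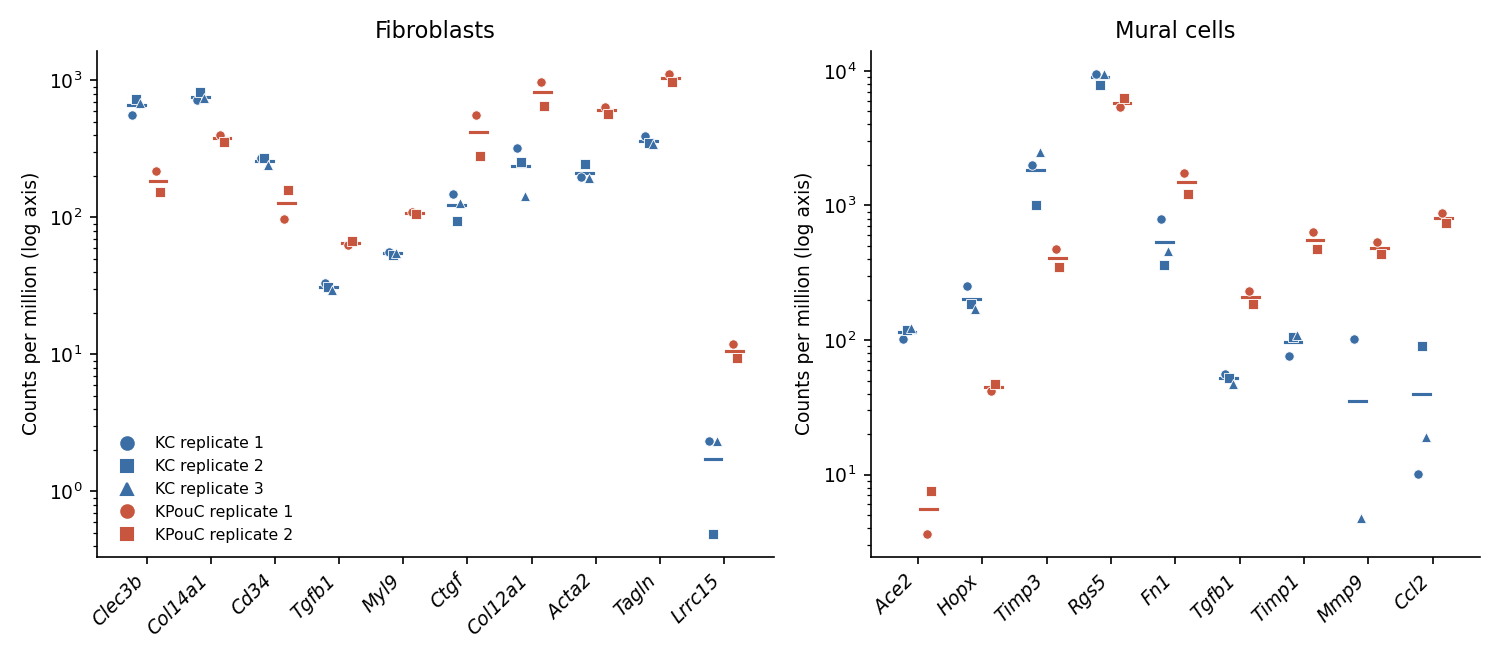
CPM of named genes in fibroblasts and mural cells on log axes, with 1 point per library and a line at the group mean; KC replicate 2 has 0 Mmp9 counts and is not drawn there. Acta2 lies near 211 in KC fibroblasts and 604 in KPouC fibroblasts, and Ace2 in mural cells near 115 and 5.57.

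Mural cells of KPouC mice carried more Ccl2, Ccl7, Mmp9 and matrix transcripts, while Ace2 fell. Ccl2 rose from 39.9 ± 44.1 to 805 ± 97.2 CPM, a log2 change of 4.31 (edgeR adjusted p = 0.000663). Ccl7 had 0 counts in KC and 771 in KPouC, at least 52.4-fold higher against a floor of 3 counts over the group. Timp1 (chromosome X, 20870166 to 20874735) rose from 96.7 to 552 CPM (edgeR adjusted p = 0.000437), Tgfb1 by 2.00 on the log2 scale, Mmp9 by 3.82, Tnc by 1.88, Fn1 by 1.47 and Col1a1 by 1.61. Ace2 fell from 115 to 5.57 CPM, a log2 change of -4.24 (edgeR adjusted p = 0.000437), and Hopx, Timp3 and C1s1 fell by 2.17, 2.16 and 1.63. Those genes kept their call with each library left out, although Mmp9 lost it by DESeq2. Rgs5 fell by 0.63 and lost its call without KC replicate 1, KC replicate 3 or KPouC replicate 1, with adjusted p up to 0.0969. The KC libraries held 49, 41 and 45 mural cells and the KPouC libraries 180 and 307. Lyz2, which rose by 3.88, lay under 10% of its level in macrophages.

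Of 3799 genes tested in mural cells, edgeR called 204 higher and 199 lower, and DESeq2 162 and 121. All 403 lacked overlap between groups, as did 43.8% of tested genes, where chance gives 20%. The total was 810 with every gene that had a count, 623 with a stricter cell filter, 176 with mouse number series as covariate, 252 without KC replicate 1, 239 without KC replicate 3 and 198 without KPouC replicate 1. Of 48 named mural genes that passed, 27 kept their call with each library left out, and calls lost numbered 12, 7 and 9 without KC replicates 1 to 3, and 17 and 6 without KPouC replicates 1 and 2. The matrix list rose, with 7 of 16 higher (8 higher and 1 lower adjusted over the list alone). Camera gave adjusted p = 3.41e-05, and adjusted p = 0.531 with an estimated correlation. Fibroblast markers in mural cells had a median log2 change of 0.24, with 1 of 4 called higher. Col1a1, Col1a2, Col3a1, Dcn and Lum are on both the matrix and the fibroblast marker list. The myofibroblast list rose, with 5 of 16 higher and 1 lower (6 and 1 adjusted over the list alone), adjusted p = 0.0203 by camera, and adjusted p = 0.712 with an estimated correlation. NF-kB genes rose, with 2 of 5 higher (5 adjusted over the list alone), adjusted p = 2.23e-05 by camera, and adjusted p = 0.451 with an estimated correlation. TGF-beta pathway genes rose, with 2 of 8 higher (3 adjusted over the list alone), adjusted p = 0.00118 by camera, and adjusted p = 0.531 with an estimated correlation. Hypoxia and glycolysis genes rose, with 3 of 7 higher (5 adjusted over the list alone), adjusted p = 0.000448 by camera, and adjusted p = 0.611 with an estimated correlation.

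Endothelial cells of KPouC mice gained Timp1, Pmepa1 and Cyp26a1 and lost Car4, Hmcn1, Fabp5 and Ptgs1, the last of which encodes a prostaglandin synthase. Timp1 rose from 14.2 ± 2.53 to 124 ± 12.9 CPM, a log2 change of 3.12 (edgeR adjusted p = 1.64e-06), though this was under 10% of its level in fibroblasts. Pmepa1 rose by 1.49 and Ms4a6d by 4.25. Ptgs1 fell from 126 ± 6.27 to 52.0 ± 0.311, a log2 change of -1.27 (edgeR adjusted p = 0.000255). Car4 fell by 2.97, Hmcn1 by 3.09, Fabp5 by 1.76 and Cysltr1 by 1.31. Each of these kept its call with any library left out. Slco2a1, a prostaglandin transporter gene that leads cluster c14, rose by 0.59 and lost its call without KC replicate 1, KPouC replicate 1 or KPouC replicate 2, with adjusted p up to 0.227. In clusters c13 and c14 alone Slco2a1 changed by 0.53 and 0.17, neither past the threshold. Serpine1 rose by 2.81 and Sele by 3.35, and both lost their call without KPouC replicate 2, at adjusted p = 0.0772 and 0.177. Tgfb1 rose by 0.64, had the opposite sign in c13 alone and lost its call without any library except KC replicate 2, with adjusted p up to 0.232. Car4 lay under 10% of its level in neutrophils.

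Of 8138 genes tested in endothelial cells, edgeR called 427 higher and 440 lower, and DESeq2 205 and 225. Groups did not overlap for 865 of the calls and for 42.2% of tested genes, where chance gives 20%. The total of 867 was 638 with mouse number series as covariate, 562 without KC replicate 1, 540 without KPouC replicate 1 and 314 without KPouC replicate 2. Of 62 named endothelial genes that passed, 29 kept their call with each library left out, and calls lost numbered 11, 6 and 9 without KC replicates 1 to 3, and 17 and 31 without KPouC replicates 1 and 2. Car8, among the 29 that kept their call, was tested in only 4 of the fits with a library left out. Cluster c13 fell from 66.7% to 32.4% of the class. Of the class calls tested there, 97.8% had the same sign, and 98.5% in c14, both parts of the class. Called there with that sign were 295 of 754 in c13 and 251 of 755 in c14. Interferon response genes fell, with 5 of 14 lower (7 adjusted over the list alone), adjusted p = 0.00136 by camera, and adjusted p = 0.712 with an estimated correlation. The matrix list rose through Bgn and Timp1, 2 of 5 (3 adjusted over the list alone), with adjusted p = 6.70e-06 by camera, and adjusted p = 0.451 with an estimated correlation. NF-kB genes rose, with 3 of 6 higher (3 adjusted over the list alone), adjusted p = 0.00394 by camera, and adjusted p = 0.531 with an estimated correlation. TGF-beta pathway genes rose, with 4 of 9 higher and 1 lower (5 and 1 adjusted over the list alone), adjusted p = 0.0027 by camera, and adjusted p = 0.451 with an estimated correlation. Leukocyte transcripts fell, with 2 of 5 lower (3 adjusted over the list alone), adjusted p = 0.000134 by camera, and adjusted p = 0.531 with an estimated correlation; its called genes Cd52 and Coro1a lay under 10% of their level in B cells, and Coro1a lost its call without KPouC replicate 2, at adjusted p = 0.0752. By camera the interferon list lost its call without KPouC replicate 1 (adjusted p = 0.189), and NF-kB without KPouC replicate 2 (adjusted p = 0.0541).

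Few genes differed in the other classes. In dendritic cells edgeR called 9 of 7952 genes higher, among them C1qc, Cd14 and Mmp12, which lay under 10% of their level in another class, and 3 lower. Unadjusted, 213 were higher and 226 lower, and DESeq2 called 10 and 4. The total of 12 was 0 without KC replicate 1, 6 without KC replicate 2, 1 without KC replicate 3 and 74 without KPouC replicate 1, and 1 gene was left without genes at under 10% of another class. In B cells edgeR called Cirbp, Rbm3 and the unnamed gene model Gm26825 higher and Clps, Lars2, Trp53 and Fam43a lower among 8244, and DESeq2 called 0 and 0. Unadjusted, 300 were higher and 382 lower. No named B cell or dendritic cell gene kept its call with each library left out, and Cirbp and Trp53 lost theirs without KPouC replicate 1, at an adjusted p up to 0.763, and with mouse number series as covariate, where 2 B cell genes passed. The B cell total of 7 was 27 without KC replicate 3, 0 without KPouC replicate 1 and 4 without KPouC replicate 2. In monocytes Fabp5 rose by 1.38, from 298 ± 33.6 to 778 ± 58.8 CPM (edgeR adjusted p = 0.00822), and was the 1 gene called of 6052. Unadjusted, 226 were higher and 219 lower in monocytes, and DESeq2 called 1 and 1. Monocyte calls numbered 0 without each of KC replicates 1, 2 and 3, 111 without KPouC replicate 1 and 4 without KPouC replicate 2.

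In T cells edgeR called 0 of 9879 genes higher and 0 lower, with 205 and 230 unadjusted, and DESeq2 called 1 and 2; without KC replicate 1 edgeR called 1. In neutrophils edgeR called 0 of 3998 genes higher and 0 lower, with 199 and 252 unadjusted, and DESeq2 called 4 and 2. EdgeR called 4 neutrophil genes with mouse number series as covariate, 56 without KPouC replicate 1 and 127 without KPouC replicate 2. In gamma-delta T or innate lymphoid cells edgeR called 0 of 1387 genes higher and 0 lower, with 29 and 33 unadjusted, and DESeq2 called 0 and 0.

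Gene lists moved in these classes with few or no single genes called. Interferon response genes fell in T cells (0 of 18, or 4 adjusted over the list alone), with adjusted p = 1.51e-09 by camera and adjusted p = 0.531 with an estimated correlation. They also fell in B cells (0 of 12, or 1 adjusted over the list alone), with adjusted p = 0.0027 by camera and adjusted p = 0.722 with an estimated correlation. The T cell class included cluster c28, led by interferon genes such as Ifit1, at 1.61%, 4.28% and 1.17% of it in KC replicates 1 to 3 and 0.734% and 0% in KPouC, so the change in its list includes a change in mix. The B cell class included the similar cluster c31, at 0.710%, 6.81% and 0.680% in KC and 1.02% and 0% in KPouC. KC replicate 2 stood apart in both. T cells had the hypoxia list (0 of 14, 0 adjusted over the list alone), the matrix list (0 of 7, 0 adjusted over the list alone) and the proliferation list (0 of 15, 0 adjusted over the list alone) higher. Camera gave these adjusted p = 0.00293, 0.0213 and 0.0209, and adjusted p = 0.619, 0.531 and 0.798 with an estimated correlation. The proliferation list fell in T cells without KPouC replicate 2, at adjusted p = 0.111. By camera the interferon list in B cells lost its call without KC replicate 2 or KPouC replicate 2 (adjusted p = 0.251 and 0.0620), and in T cells it kept its call with each library left out. In T cells the matrix list lost its call without KC replicate 2 or KPouC replicate 1 (camera adjusted p = 0.0739 and 0.740), hypoxia without KPouC replicate 2 (0.361) and proliferation also without KC replicate 3 (0.228).

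B cells had lipid-associated (0 of 7, 3 adjusted over the list alone), MHC class II (0 of 9, 0 adjusted over the list alone) and leukocyte genes (0 of 7, 1 adjusted over the list alone) higher, and TGF-beta pathway genes (0 of 6, 2 adjusted over the list alone) lower. Camera gave adjusted p = 5.05e-05, 0.00313, 0.0235 and 0.00528 in that order, and adjusted p = 0.451, 0.572, 0.619 and 0.489 with an estimated correlation. Dendritic cells had complement (1 of 7, 3 adjusted over the list alone), NF-kB (0 of 16, 2 adjusted over the list alone), lipid-associated (0 of 11, 2 adjusted over the list alone) and hypoxia genes (0 of 12, 0 adjusted over the list alone) higher. Camera gave adjusted p = 1.05e-12, 2.88e-07, 0.00215 and 0.00313, and adjusted p = 0.451, 0.572, 0.451 and 0.572 with an estimated correlation. Macrophage markers moved with them in dendritic cells, with 1 of 6 called higher by edgeR and a median log2 change of 1.95. C1qa, C1qb and C1qc are on both the complement and the macrophage marker list, so these markers are no separate evidence. Macrophage markers in B cells had a median log2 change of 0.39, with 0 of 3 called by edgeR. By camera TGF-beta in B cells lost its call without KPouC replicate 1 (adjusted p = 0.475), and leukocyte genes without KC replicate 2 or KPouC replicate 2 (0.0735 and 0.238). In dendritic cells the lipid-associated and hypoxia lists lost theirs without KPouC replicate 2 (camera adjusted p = 0.203 and 0.369).

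Monocytes had hypoxia (0 of 12, 0 adjusted over the list alone), NF-kB (0 of 17, 0 adjusted over the list alone), lipid-associated (1 of 11, 1 adjusted over the list alone), neutrophil maturation (0 of 7, 0 adjusted over the list alone) and immediate early genes (0 of 16, 0 adjusted over the list alone) higher, and MHC class II genes (0 of 10, 2 adjusted over the list alone) lower. Camera gave adjusted p = 3.41e-05, 0.000627, 0.0027, 0.0247, 0.00632 and 0.0245, and adjusted p = 0.619, 0.728, 0.690, 0.531, 0.798 and 0.706 with an estimated correlation. Without KPouC replicate 2, 4 of these monocyte lists changed direction, NF-kB and immediate early genes at adjusted p = 0.00461 and 0.0196, and lipid-associated and neutrophil maturation genes at 0.839 for both. Neutrophils had lipid-associated genes (0 of 9, 1 adjusted over the list alone) higher, with adjusted p = 0.0285 by camera and adjusted p = 0.572 with an estimated correlation, and macrophage markers there had a median log2 change of 0.94. Gamma-delta T or innate lymphoid cells had immediate early genes (0 of 10, 0 adjusted over the list alone) lower, with adjusted p = 0.00367 by camera and adjusted p = 0.688 with an estimated correlation. By camera, monocyte calls were also lost for MHC class II without KC replicate 1 or KPouC replicate 2 (adjusted p = 0.210 and 0.120), NF-kB without KC replicate 3 (0.0720), hypoxia without KPouC replicate 2 (0.168), neutrophil maturation without KC replicate 1 (0.128) and immediate early genes without KC replicate 1 or KC replicate 3 (0.105 and 0.109). The neutrophil call was lost without KC replicate 1, KC replicate 2 or KPouC replicate 1 (camera adjusted p = 0.158, 0.0506 and 0.0728), and the gamma-delta T or innate lymphoid call without KC replicate 2 (0.214).

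The mitochondrial list, a measure of cell quality, was higher in KPouC in 7 classes, namely B cells, T cells, dendritic cells, fibroblasts, macrophages, monocytes and gamma-delta T or innate lymphoid cells. Single genes were called in none of them, and 7 of 9 adjusted over the list alone in the last and 0 in the others. Camera's adjusted p ranged from 7.84e-11 in gamma-delta T or innate lymphoid cells to 0.00847 in B cells, and adjusted p = 0.531 and 0.761 with an estimated correlation in these. In B cells the direction changed without KPouC replicate 1, at adjusted p = 0.489. The eicosanoid synthesis, eicosanoid receptor, tuft cell marker, cytotoxicity, type 2 immunity, stromal and sex-linked lists were called in no class tested. The ductal, erythroid and endocrine lists had too few tested members in every class. By camera the mitochondrial list lost its call without KC replicate 1 in B cells, T cells and macrophages (adjusted p = 0.225, 0.0681 and 0.0960), and without KPouC replicate 1 in T cells, dendritic cells, macrophages and monocytes (0.893, 0.450, 0.242 and 0.0796).

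Eicosanoid genes were spread over distinct classes, given here as mean CPM ± SD over the 5 libraries. Ptgs2 was highest in neutrophils, at 2008 ± 895, Ptgis in fibroblasts, at 344 ± 82.7, and Slco2a1 in endothelial cells, at 377 ± 90.2. Hpgds was highest in macrophages, at 52.4 ± 16.3, as was Tbxas1, at 114 ± 14.2, and Alox5 in neutrophils, at 105 ± 24.0. Ltc4s reached 338 ± 92.4 in neutrophils and 143 ± 19.2 in macrophages. Ptger3 was highest in fibroblasts, at 107 ± 42.3, Ptger4 in dendritic cells, at 54.9 ± 7.08, and Cysltr1 in monocytes, at 137 ± 22.9. The prostaglandin D2 receptor gene Ptgdr gave 6 counts in fibroblasts, 1 in dendritic cells and none in the other tested classes, and Ptgdr2 gave 6 in dendritic cells and 1 each in macrophages and mural cells, so neither was measurable at this depth. Ptgs1 in macrophages did not differ between genotypes (86.5 and 87.4, edgeR adjusted p = 0.967), and Ptger4 in fibroblasts was lower without passing the threshold (24.2 and 13.8, edgeR adjusted p = 0.0588).

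The genotype effect differed between fibroblasts and macrophages for 239 of 12726 genes by edgeR's interaction test, 125 in the direction of fibroblasts and 114 in that of macrophages. The total was 104 without KC replicate 1, 79 without KC replicate 2 and 134 without KPouC replicate 1. Ccl8 changed by -1.92 in macrophages and 0.43 in fibroblasts, a difference of 2.36 (edgeR adjusted p = 0.000577). Gpnmb changed by -1.65 and 0.83, a difference of 2.36 (edgeR adjusted p = 0.000624), and Timp1 rose further in fibroblasts, by 0.86.

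Sorted tuft cells of KC mice expressed tuft cell genes and enzymes of leukotriene and prostaglandin synthesis. Reads per cell ran from 9428 to 2073790 with a median of 246794, and genes per cell from 227 to 5813 with a median of 1233. Of 139 cells, 120 had a read of Trpm5 (86.3%, exact 95% interval 79.5 to 91.6), and 120 one of Dclk1. Pou2f3 was read in 57 cells (41.0%, 32.7 to 49.7). Alox5 was read in 113 cells (81.3%, 73.8 to 87.4), Ltc4s in 118 (84.9%, 77.8 to 90.4), and both together in 105 (75.5%, 67.5 to 82.4). Ptgs1 was read in 74 cells (53.2%, 44.6 to 61.7), Hpgds in 80 (57.6%, 48.9 to 65.9), and both together in 53 (38.1%, 30.0 to 46.8). Ptgs2 was read in 6 cells and Il25 in 4. Of 23 tuft cell markers listed in the file, 15 were read in at least 50% of cells. So were 5 of 13 eicosanoid synthesis genes and 0 of 3 eicosanoid receptor genes listed there. The full lists hold 24, 19 and 15 genes in that order, and the members absent from the file are not counted. At least 5 tuft markers were read in 129 cells (92.8%, 87.2 to 96.5), and fewer than 3 in 5 cells.

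Krt18 and Krt8 ranked 1 and 3 by mean value in tuft cells, and were read in 136 and 135 cells. Epcam, used for the sort, was read in 116 cells, Siglecf, also used, in 74, and the leukocyte gene Ptprc in 20 (14.4%, 9.02 to 21.3). The acinar genes Spink1 and Ctrb1 were read in 79 and 41 cells. The highest share of any gene was 56.8% in the acinar list (Spink1), 97.8% in the ductal list (Krt18), 14.4% in the leukocyte list (Ptprc), 11.5% in the endocrine list (Ins2) and 3.60% in the stromal list (Col1a1 and Pecam1), and no erythroid gene was listed. Genes absent from the file, such as Ptges, Ptgds and Ptger4, give no value, because it lists only genes seen in at least 3 cells.

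**Figure D4:**
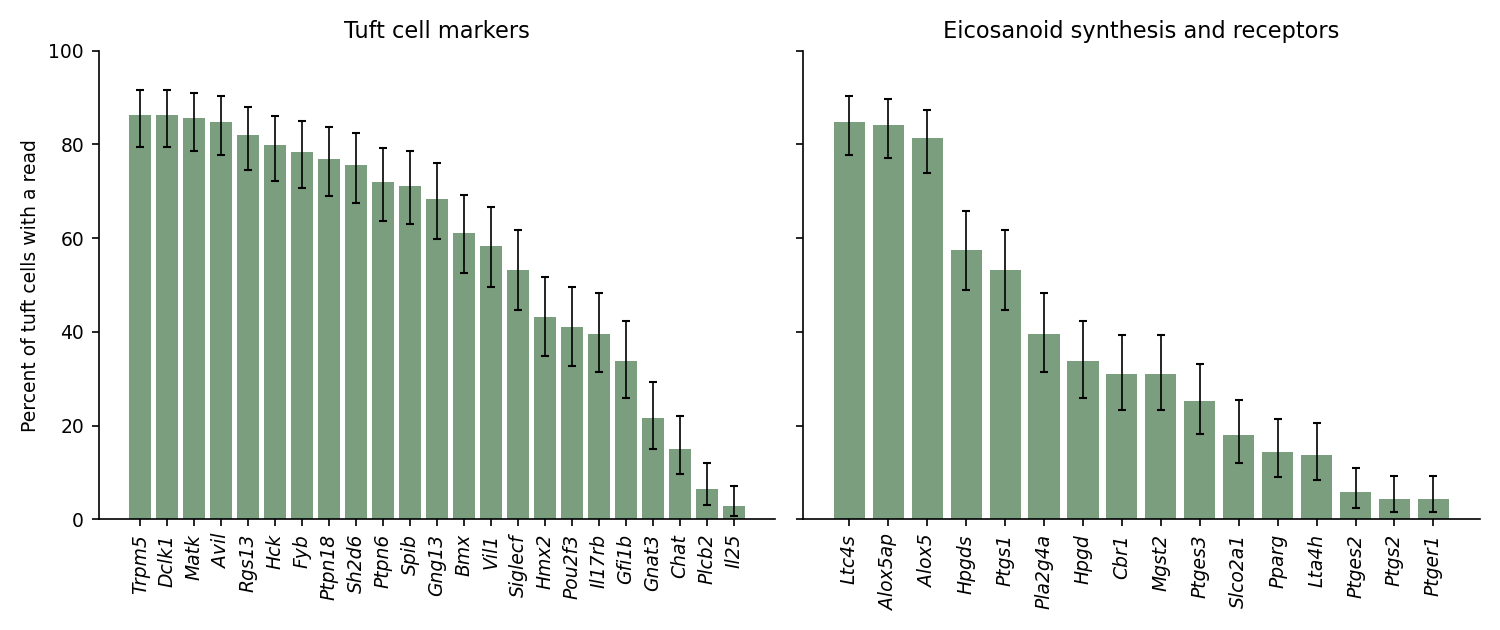
Percent of 139 tuft cells with a read of each tuft cell marker and eicosanoid gene listed in the file; bars start at 0 and error bars are exact 95% intervals. Ltc4s and Alox5 stand at 84.9% and 81.3%, and Ptgs2 at 4.32%.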

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

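The interaction test between fibroblasts and macrophages was planned. In this part 2 tests were stated before their result was seen, the share of acinar counts in a small part of the macrophages and the depth of KPouC replicate 2. The tests of free RNA, of droplet depth, of the percent of macrophages with an acinar count, of genotype, of lymph node tissue, of cluster mix and of single libraries were chosen after it.

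The genotype effect differed between fibroblasts and macrophages by edgeR's interaction test for 239 genes, 20 of them among the 123 named genes tested. Fibroblasts lay above macrophages in log2 change for Cpa1 (4.75), Trem2 (2.48), Ccl4 (2.47), Gpnmb (2.36), Ccl8 (2.36), Cela1 (2.00), Cxcl10 (1.89), Stab1 (1.88), Thy1 (1.31), Timp1 (0.86), Cnn2 (0.77) and Tgfbr2 (0.67). They lay below for Ccl5 (-5.40), G0s2 (-2.73), Cd34 (-1.46), Slco2b1 (-1.39), Tnfaip2 (-1.38), Col14a1 (-1.35), Ndrg1 (-1.13) and Cd9 (-0.90). Cpa1 and Cela1 are acinar genes, and Trem2, Ccl4 and Ccl5 in fibroblasts lay under 10% of their level in a leukocyte class.

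Cluster c26, which no comparison of gene expression used, held 1.33% ± 0.141 of CD45-positive cells in KPouC and 0.135% ± 0.0756 in KC. It held 111 cells, and its leading genes included Chil3, Car4, Atp6v0d2, Arg1, Alox15, Plet1 and Marco, some of which also rose in KPouC macrophages. Its cell type was left unnamed.

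Acinar transcripts were more frequent in KC macrophages than in KC T cells, the only class they were tested against. In KC replicates 1 to 3, 13.95%, 19.78% and 16.98% of neutrophils had an acinar count, at median depths of 1281, 1358 and 1421.5. Per 10000 counts, neutrophils held 3.41, 2.337 and 4.745 acinar counts and macrophages 3.162, 3.626 and 6.259. The excess over T cells is thus not shown to be particular to macrophages. Free acinar RNA taken up equally by all droplets would give like percents. Yet the ratio of macrophages to T cells was at least 3.48 in each KC library. It was at least 2.78 with every droplet thinned to 2000 counts, which argues against deeper droplets as the whole cause. Earlier forms of the free RNA and depth tests decided neither: mean acinar counts per droplet, macrophages over T cells, were 10.2, 1.49 and 5.93 times in KC replicates 1 to 3, and per 10000 counts 4.66, 0.843 and 3.48 times. Doublets of a macrophage and an acinar cell stay open for the number of counts. Of these counts, 67.7% lay in 5% of KC macrophages, over the 50% set beforehand. T cell counts were more concentrated in each KC library (76.4% to 94.3%), but only 10.3%, 13.6% and 11.2% of T cells had any. Fewer cells with a count alone raise that share, so the comparison decides nothing about doublets. The 85 macrophages of that 5% held a median of 14 acinar counts. For the percent with a count, the thinned ratio without that 5% was at least 2.34. That 5% is too small a part to make the percents alike, so this ratio decides nothing about doublets in a larger part. Uptake of acinar debris by macrophages stays open as an untested hypothesis.

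T cells were scarce in KPouC replicate 2 and not in KPouC replicate 1, which restates the pattern and so decides nothing about genotype. T cells were 33.0% of CD45-positive cells in KPouC replicate 1, within the KC range, but B cells (21.5%, lowest KC library 21.7%) and NK cells (0.315%, lowest KC library 0.560%) lay under it, so genotype stays open; the test was first read on T cells alone. Loss of droplets with few counts in KPouC replicate 2 is argued against, since the 5th percentile of counts per cell there was 980.8, under the median of 2919 of T cells in the other libraries. Less lymph node tissue in this library may explain its low T cell share, as the naive-type clusters c2 and c3 made up 48.2% of its T cells against 66.1% to 78.1% elsewhere, and a difference between the 2 KPouC mice themselves was not tested.

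Many genes changed in macrophages. A change in the mix of c1, c4 and c15 is argued against as the whole cause. The median ratio of the log2 change within cluster to that in the class was 0.655 or more in c1 and c4. Single genes such as Cd163 and Lyve1 did not fall within c4. A change in mix inside a cluster stays open, since this ratio cannot see it. With the stricter cell filter, a cluster led by Mmp12 and Plet1 held 42, 71 and 24 KC cells and 374 and 566 KPouC cells. Another, led by Retnla and Ear2, held 164, 249 and 157 KC cells and 329 and 239 KPouC cells. Calls with 1 KPouC library left cannot decide whether a single KPouC library is the whole cause. The lone sample was there assumed to vary like the other group. Such fits also called genes in neutrophils, where the fit of all libraries called 0. In 43.2% of tested macrophage genes both KPouC libraries lay on 1 side of every KC library, where chance gives 20%. The KPouC genotype stays open, beside any difference that follows the groups and is not recorded in the labels.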

How the results depend on the processing

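The sex-linked covariate, the removal of genes at under 10% of another class, clusters fitted alone, the non-lymphoid denominator and the counting of c17 as fibroblasts were chosen after the data were seen. Where 1 KPouC library was left, the lone sample was assumed to vary like the other group. The cause of the changes below was not tested unless given.

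Of 3689 values of named genes under alternatives, 2855 kept their direction and side of the threshold, 820 kept direction and lost the call, and 14 reversed. Of 784 values of called gene lists, 598 were the same, 178 lost the call and 8 reversed. For tuft cells, 303 of 321 values moved by less than their interval. Of 540 group means of eicosanoid genes per class, 65 moved by more than 1 SD between libraries, 40 of 286 without doublet removal and 25 of 254 at Leiden resolution 0.5.

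With every gene that had a count tested, genes called were 58 in B cells, 74 in T cells, 113 in dendritic cells, 1197 in fibroblasts, 7 in gamma-delta T or innate lymphoid cells, 1778 in macrophages, 107 in monocytes, 810 in mural cells, 100 in neutrophils and 589 for the interaction. DESeq2 called 0 in B cells, 3 in T cells, 430 in endothelial cells, 440 in fibroblasts, 2 in monocytes and 6 in neutrophils. With mouse number series as covariate there were 2 in B cells, 110 in fibroblasts, 176 in mural cells and 4 in neutrophils. With the sex-linked pattern as covariate there were 16 in B cells, 22 in dendritic cells, 694 in fibroblasts, 37 in monocytes and 2 in neutrophils. With equal cells per library there were 0 in B cells, 506 in macrophages and 0 in monocytes, from fewer cells. Without doublet removal there were 0 in dendritic cells and 6 in neutrophils. With the stricter cell filter there were 0 in dendritic cells, 1 in gamma-delta T or innate lymphoid cells, 1486 in macrophages and 623 in mural cells. At Leiden resolution 0.5 there were 4 in dendritic cells and 583 in fibroblasts, and no separate monocyte or mesothelial class gave a value. Without genes at under 10% of another class there were 1 in dendritic cells and 2 in neutrophils. Clusters alone, each with fewer cells than its class, gave 116 in c1, 84 in c4, 34 in c15, 15 in c5, 132 in c6, 20 in c11, 406 in c13 and 289 in c14. Whether cell number sets these counts was not tested. Lists called were 0 with an estimated correlation and 1 by fry.

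Reversed in clusters alone were Tgfb1 in c13 (-0.0204), Cd80 (-0.41), Lta4h (-0.11), Cd163 (0.46), Ccl24 (-0.79), Lyve1 (0.12), Cd274 (-0.81) and C4b (0.31) in c4, Arg1 (-0.17) in c1 and Sell (0.0055) in c15. In fibroblasts Slpi reversed without doublet removal (-0.12) and with the stricter filter (-0.16), Ccl4 without doublet removal (-0.0471) and Clps with the stricter filter (0.55), where the acinar list also reversed (camera adjusted p = 0.0557). The mitochondrial list reversed in B cells without KPouC replicate 1 (0.489). Without KPouC replicate 2 the proliferation list reversed in T cells (0.111) and fibroblasts (0.749), and in monocytes NF-kB (0.00461), lipid-associated (0.839), neutrophil maturation (0.839) and immediate early genes (0.0196). With each library left out, the adjusted p of these lists ranged from 4.66e-07 to 0.489 for the mitochondrial list in B cells, 9.06e-10 to 0.228 and 1.03e-06 to 0.749 for proliferation in T cells and fibroblasts, and in monocytes 1.30e-32 to 0.0720 for NF-kB, 5.56e-08 to 0.839 for lipid-associated, 5.04e-08 to 0.839 for neutrophil maturation and 6.90e-14 to 0.109 for immediate early genes, whichever the direction.

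With each library left out in turn, genes called ranged from 0 to 27 in B cells, 0 to 1 in T cells, 0 to 74 in dendritic cells, 314 to 752 in endothelial cells, 60 to 207 in fibroblasts, 0 to 0 in gamma-delta T or innate lymphoid cells, 324 to 644 in macrophages, 0 to 111 in monocytes, 198 to 375 in mural cells, 0 to 127 in neutrophils and 79 to 238 for the interaction, and lists called from 56 to 73. Differences in share, in percentage points, ranged from -20.8 to -3.58 for B cells, -0.454 to -0.279 for NK cells, -30.3 to -1.70 for T cells, -2.27 to -1.11 for dendritic cells, -6.84 to -1.71 for endothelial cells, -27.1 to -19.5 for fibroblasts, -0.544 to -0.0885 for gamma-delta T or innate lymphoid cells, 6.73 to 35.9 for macrophages, -0.154 to 0.451 for mesothelial cells, 0.364 to 6.57 for monocytes, 15.8 to 16.2 for mural cells, -0.0083 to 8.39 for neutrophils, -1.66 to 1.59 for plasma cells and -0.495 to -0.196 for plasmacytoid dendritic cells. Reversed without KPouC replicate 2 were mesothelial cells (-0.154), neutrophils (-0.0083) and plasma cells (1.59), and plasma cells also without KC replicate 2 (0.708) and as percent of all cells (0.0127). EdgeR on cell counts called fibroblasts (-0.62) and mural cells (2.21), which the exact test with 10 splits cannot.

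Depth limits Ptgdr and Ptgdr2 and the classes of few cells. Both genes, and Pou2f3, had at most 7 counts in any class or library given here. For Pou2f3 the sort is the limit, since it left out the EpCAM-positive epithelium in which Ptf1aCre acts.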

Other observations

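Trpm5 gave 10, 0 and 1 counts in KC replicates 1 to 3 and 0 and 0 in KPouC replicates 1 and 2. Epcam gave 140, 172 and 121 counts in KC and 391 and 303 in KPouC, in cells sorted as EpCAM-negative. Cells in unnamed clusters were 6.15%, 7.71% and 7.56% of KC replicates 1 to 3 and 9.37% and 12.8% of KPouC replicates 1 and 2. The unnamed cluster c33, led by adipocyte genes, held 44 cells. In tuft cells with a read of Ptprc, 16 of 20 had at least 5 tuft markers.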
